A study of Brassica rapa subsp. pekinensis with 2 samples.

How the data were processed

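Small RNA libraries were made from fully expanded petals of Chinese cabbage (Brassica rapa subsp. pekinensis) collected at flowering, 1 library from doubled haploid plants and 1 from autotetraploid plants. A doubled haploid carries 2 identical chromosome sets obtained by doubling a haploid genome, and an autotetraploid carries 4 sets of the same genome. Both came from the doubled haploid line FT and were grown alike, per the labels' protocols. RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit for Illumina, per the labels' protocols. Bowtie is named in the submitters' processing notes without a version or a role. The genome build, the miRBase release, the program that predicted miRNAs without a miRBase name and the statistical test were not given in the sources used here.

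The deposited table held 34 miRNAs, and its title line called them differentially expressed between both ploidy levels. miRNAs outside this list were not analysed here, so nothing is reported on families that the list lacks. For each miRNA the authors deposited a value per library labelled TPM. These deposited values behaved as RPM, reads divided by a normalising total of their library: all 65 deposited values above 0 were whole multiples, within 0.001 of a read, of 1 step per library. One read was worth 2.21 RPM in the autotetraploid and 2.32 RPM in the doubled haploid library. The deposited log2 fold change was the log2 of the autotetraploid over the doubled haploid value, with 0.5 in place of a 0. The table also gave the authors' p-values and q-values, the latter by Storey's method, per the file headers. In the authors' deposited table the smallest absolute log2 fold change was 1.0034 and the largest q-value 0.0096073, so every listed miRNA passed a 2-fold difference and a q-value of 0.01.

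With 1 library per group there was no replicate, so no test between ploidy levels was run and no p-value is given apart from those in the authors' deposited table. The step per library was used to turn RPM into implied reads. The ratio of both libraries was given a 95% interval from the exact (Clopper-Pearson) binomial split of the implied reads. These intervals cover counting error only, and no molecular identifiers are mentioned in the labels, so the intervals leave out variation between plants, RNA preparations and amplifications. A 0 was set at a floor of 3 reads, which is 6.64 RPM in the autotetraploid and 6.95 RPM in the doubled haploid library. The fold at that floor takes the reads of the other library as exact, so it is no lower bound on the ratio. Values of 1 read lie under that floor but were kept as they are, so their ratios were not set against it. The design had allowed for a table of all miRNAs. Log2 ratios for counts and medians used a pseudocount of 1 RPM and miRNAs whose higher value was at least 10 RPM, which 32 of the 34 met. Medians with a 0 set at the floor used no pseudocount.

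Before the data were examined, 15 lists were fixed by miRNA family number: phase change and flowering, TCP, MYB and GRF regulation, organ boundary and polarity, auxin signalling, NF-YA and GRAS regulation, sulfate and phosphate, copper, small RNA machinery, PPR, NLR and phasiRNA triggers, MYB and anthocyanin, MADS AGL16, Brassica-named miRNAs, other Brassicaceae miRNAs, miRNAs without a miRBase name, and pollen and stamen markers. The naming rule took the 10 miRNAs with the largest log2 ratio each way at 10 RPM or more, the 10 most abundant of each library, and up to 4 members per list. The listed miRNAs under 10 RPM, bra-miR172d-5p and bra-miR9555a-3p, fall outside the first part of that rule and are given because the lower group is small. Names were matched to the RefSeq annotation CAAS_Brap_v3.01, which held a gene for 18 of the 19 miRBase-named rows and none for bra-miR172b-5p. No coordinates are given, because the build behind the table was not stated. The 15 rows without a miRBase name carry only the label novel_ and a number, with no sequence or position.

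The alternatives covered the pseudocount (0.1 and 10), the filter on low values, the fold threshold, totals without the 3 most abundant miRNAs and omission of the less abundant arm of a hairpin. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 drew the plot. On simulated reads of the 34 miRNAs (200 draws), 96.6% of the intervals held a true ratio of 1, 96.7% a ratio of 2 and 96.8% a ratio of 4. Those draws were not selected for a difference, as the listed miRNAs were, so coverage after selection was not measured.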

Results

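The study asked how miRNA abundance in petals differs between doubled haploid and autotetraploid Chinese cabbage derived from one line. The list of 34 miRNAs held 19 with miRBase names and 15 predicted miRNAs known only by a number (novel_23 and the like). It accounted for 58062 implied reads in the autotetraploid and 20230 in the doubled haploid library. From the value of 1 read, the reads had been divided by a normalising total of 451878 in the autotetraploid and 431681 in the doubled haploid library. No replicate library stands behind any value below, and every difference is between these 2 libraries.

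In the autotetraploid petal library, 24 of the 34 listed miRNAs were higher and 10 were lower than in the doubled haploid library. The most abundant listed miRNAs of the autotetraploid library, bra-miR408-5p and bra-miR398-3p, were both about 4-fold higher there. In the doubled haploid library bra-miR408-5p also came first, and novel_23 stood above bra-miR398-3p. bra-miR156a-5p, bra-miR172c-3p, bra-miR171a and bra-miR395d-3p were 2.12-fold to 2.80-fold higher in the autotetraploid library. The most abundant miRNA that was lower in the autotetraploid was novel_23, at 4132 RPM against 12213 RPM. The list was chosen by the authors on these same libraries for a difference of at least 2-fold, so the counts are not independent evidence of a direction. Counting intervals excluded a ratio of 1 for 20 of the higher and 5 of the lower miRNAs, and included it for 9. They lay wholly beyond 2-fold for 10 of the higher and 2 of the lower miRNAs.

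**Figure D1:**
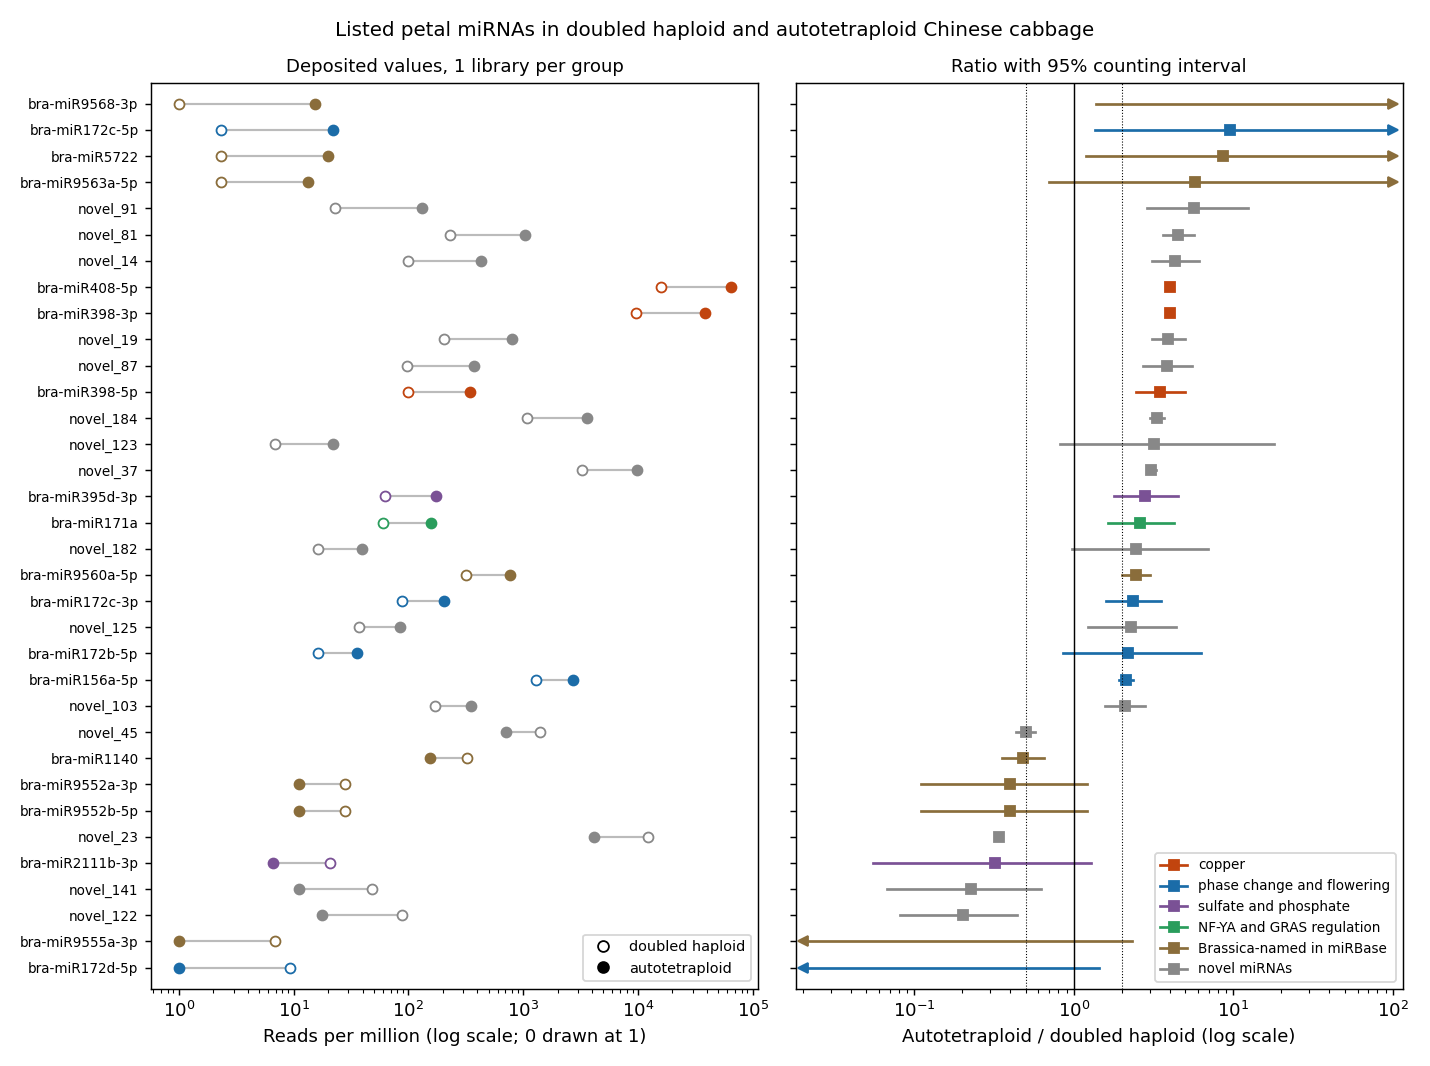
Left, deposited RPM of each listed miRNA in the doubled haploid (open circles) and autotetraploid (filled circles) petal library, on a log axis with 0 drawn at 1. Right, the ratio of autotetraploid to doubled haploid (squares) with its 95% counting interval (lines, arrows where it leaves the axis), on a log axis with a solid line at 1 and dotted lines at 0.5 and 2, where colours give the miRNA list. The abundant bra-miR408-5p and bra-miR398-3p have narrow intervals around 4.01 and 3.98, while the intervals of 9 miRNAs with few reads reach across 1.

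The 3 listed members of the copper group were all higher in the autotetraploid library. Membership went by family number, and bra-miR408-5p and bra-miR398-5p are 5p arms, whose targets were not examined. In other plants miR398 targets transcripts of copper/zinc superoxide dismutases and miR408 targets transcripts of copper proteins such as plantacyanin and laccases, and both accumulate when copper is scarce. bra-miR408-5p (RefSeq gene MIR408) stood at 64152 RPM in the autotetraploid and 16007 RPM in the doubled haploid library, a ratio of 4.01 with a counting interval from 3.90 to 4.11. bra-miR398-3p (MIR398) stood at 38041 RPM against 9551 RPM, a ratio of 3.98 with an interval from 3.85 to 4.12. The other arm of the same hairpin, bra-miR398-5p, stood at 345 RPM against 99.6 RPM, a ratio of 3.47 with an interval from 2.46 to 4.98. The median log2 ratio of the 3 was 1.99. bra-miR408-5p and bra-miR398-3p together made up 79.5% of the listed total in the autotetraploid and 54.5% in the doubled haploid library. Without them the listed miRNAs summed to 26297 RPM in the autotetraploid and 21305 RPM in the doubled haploid library.

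Of the 5 listed miRNAs of the phase change and flowering group, 4 were higher in the autotetraploid library and 1 was lower. miR156 targets transcripts of SPL transcription factors and miR172 those of APETALA2-like factors. The group was fixed by family number, so its count and medians take in 5p arms of miR172, whose targets were not examined. bra-miR156a-5p (MIR156A) stood at 2729 RPM in the autotetraploid and 1286 RPM in the doubled haploid library, a ratio of 2.12 with an interval from 1.92 to 2.35. bra-miR172c-3p (MIR172C) stood at 206 RPM against 88.0 RPM, a ratio of 2.34 with an interval from 1.59 to 3.51. The opposite arm, bra-miR172c-5p, rested on 10 reads against 1, a ratio of 9.55 with an interval from 1.36 to 415. bra-miR172b-5p rested on 16 reads against 7, a ratio of 2.18 with an interval from 0.850 to 6.28 that included 1. bra-miR172d-5p (MIR172D) had 0 reads in the autotetraploid and 4 in the doubled haploid library. With the 0 set at the floor of 3 reads it was 1.40-fold lower. Its counting interval, from 0 to 1.45, also included 1. The 4 listed miR172 rows summed to 263 RPM against 116 RPM, a ratio of 2.27 with an interval from 1.62 to 3.23. Most of that sum was bra-miR172c-3p, and the other 3 rows were 5p arms. The median log2 ratio was 1.15 over the 4 miRNAs at 10 RPM or more. Without a pseudocount it was 1.13 over all 5, with the 0 of bra-miR172d-5p set at the floor.

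bra-miR171a (MIR171A), of the family that targets GRAS transcription factors, was the only listed member of the NF-YA and GRAS group. It stood at 157 RPM in the autotetraploid and 60.2 RPM in the doubled haploid library, a ratio of 2.61 with an interval from 1.64 to 4.26. The 2 listed miRNAs of the sulfate and phosphate group went opposite ways. bra-miR395d-3p (MIR395D), of the family that targets ATP sulfurylases and a sulfate transporter, stood at 175 RPM against 62.5 RPM, a ratio of 2.80 with an interval from 1.79 to 4.50. bra-miR2111b-3p (MIR2111B), of a family that responds to phosphate starvation, rested on 3 reads in the autotetraploid and 9 in the doubled haploid library, a ratio of 0.318 with an interval from 0.0555 to 1.28 that included 1. The median log2 ratio of the pair, -0.02, describes neither member.

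The 8 listed Brassica-named miRNAs divided evenly, with 4 higher and 4 lower in the autotetraploid library. bra-miR9560a-5p (MIR9560A) stood at 768 RPM in the autotetraploid and 315 RPM in the doubled haploid library, a ratio of 2.44 with an interval from 1.99 to 2.99. bra-miR1140 (MIR1140) was lower in the autotetraploid, at 155 RPM against 322 RPM, a ratio of 0.481 with an interval from 0.356 to 0.646. The other 6 rested on few reads. bra-miR9568-3p (MIR9568) had 7 reads in the autotetraploid and 0 in the doubled haploid library. It was 2.23-fold higher with the 0 set at the floor of 3 reads, while the lower bound of its counting interval was 1.38. bra-miR5722 (MIR5722) had 9 reads against 1, a ratio of 8.60 with an interval from 1.19 to 377. bra-miR9563a-5p (MIR9563A) had 6 reads against 1, a ratio of 5.73 with an interval from 0.695 to 264 that included 1. bra-miR9552a-3p (MIR9552A) and bra-miR9552b-5p (MIR9552B) had identical values, 5 reads against 12, a ratio of 0.398 with an interval from 0.110 to 1.21 that included 1. bra-miR9555a-3p (MIR9555A) had 0 reads in the autotetraploid and 3 in the doubled haploid library, both at or under the floor, so no fold is given. The median log2 ratio was 1.28 over the 7 miRNAs at 10 RPM or more. Without a pseudocount it was 1.16 over the same 7, with the 0 of bra-miR9568-3p set at the floor. The median was 0.12 over all 8 with a pseudocount of 1, which gives bra-miR9555a-3p a value that is no bound, so the median describes no common direction.

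Among the 15 predicted miRNAs without a miRBase name, 11 were higher and 4 were lower in the autotetraploid library. novel_37 stood at 9905 RPM in the autotetraploid and 3234 RPM in the doubled haploid library, a ratio of 3.06 with an interval from 2.88 to 3.25. novel_184 stood at 3585 RPM against 1077 RPM, a ratio of 3.33 with an interval from 3.00 to 3.70. novel_81 stood at 1036 RPM against 229 RPM, a ratio of 4.52 with an interval from 3.63 to 5.67. The ratios of novel_19, novel_14, novel_87 and novel_91 were 3.92, 4.29, 3.84 and 5.64, with lower interval bounds of 3.10, 3.07, 2.73 and 2.86. novel_103 and novel_125 had ratios of 2.08 and 2.27, with lower bounds of 1.57 and 1.24. novel_182 and novel_123 had ratios of 2.46 and 3.18, and their intervals, from 0.979 and 0.820 upwards, included 1. Of the lower ones, novel_23 had a ratio of 0.338 with an interval from 0.321 to 0.357, and novel_45, at 704 RPM against 1411 RPM, a ratio of 0.499 with an interval from 0.434 to 0.572. novel_122 had 8 reads in the autotetraploid and 38 in the doubled haploid library, a ratio of 0.201 with an interval from 0.0810 to 0.438. novel_141 had 5 reads against 21, a ratio of 0.227 with an interval from 0.0670 to 0.620. The median log2 ratio of the 15 was 1.54, while their summed RPM differed by a ratio of only 1.14 because novel_23, the most abundant of them in the doubled haploid library, was lower in the autotetraploid.

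The other 9 lists, TCP, MYB and GRF regulation, organ boundary and polarity, auxin signalling, small RNA machinery, PPR, NLR and phasiRNA triggers, MYB and anthocyanin, MADS AGL16, other Brassicaceae miRNAs and pollen and stamen markers, had 0 members among the 34 miRNAs and were not analysed here. Carry-over of pollen or stamen tissue could therefore not be assessed. In the authors' deposited table the p-value was 0 for bra-miR398-3p, bra-miR408-5p, novel_23 and novel_37. It was 3.57e-83 for bra-miR156a-5p, 2.38e-09 for bra-miR172c-3p and 5.22e-09 for bra-miR171a. The largest p-value in the authors' deposited table was 0.022497, for bra-miR172b-5p, with a q-value of 0.0096073. Those p-values compare 2 libraries and carry no variation between plants.

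Across the 32 miRNAs at 10 RPM or more, the log2 values of both libraries had a Pearson r of 0.90 and a Spearman rho of 0.87. This is a correlation across miRNAs chosen for a difference, which are not independent replicates. The 10 most abundant miRNAs of each library held 98.0% of the listed total in the autotetraploid and 97.4% in the doubled haploid library.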

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

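The settings with the fitted centre, the counting intervals and the bra-miR9552 pair counted once were chosen after seeing the data, the others before. No miRNA kept in a setting changed direction, but this outcome was fixed in advance. A pseudocount, a filter or a fold threshold cannot turn a sign. The scaling shifts, 0.11 and 0.18 (log2), were smaller than the smallest listed absolute log2 fold change, 1.0034. With a pseudocount of 1 and at least 10 RPM, 24 miRNAs were at least 2-fold higher and 8 lower in the autotetraploid library. The lower count was 4 with a pseudocount of 10, 5 with totals recomputed without the 3 miRNAs of highest mean (bra-miR408-5p, bra-miR398-3p and novel_23), 3 at 100 RPM or more and 5 by counting intervals beyond 1, where the higher count stayed between 16 and 22. At 4-fold the counts were 8 and 2. Relative to the centre fitted to the deposited p-values (0.18, log2) they were 20 and 8. The log2 median of the sulfate and phosphate pair turned from -0.02 to 0.23 with a pseudocount of 10, to 0.074 without the 3 most abundant miRNAs and to 1.47 at 100 RPM, where bra-miR395d-3p alone was left. Without the 3 most abundant miRNAs only bra-miR398-5p was left of copper and miR398, at 1.89 (1.78 before rescaling). The copper median and the miR398 sum were both 1.82 relative to the fitted centre, where the miR408 sum was 1.83 and the miR156 sum 0.91, under 2-fold. The median of the predicted miRNAs was 1.01 with a pseudocount of 10 and 1.83 at 100 RPM. For rows with a 0 the fitted log2 ratio follows the pseudocount and is no bound: miR9568 gave 7.28 at 0.1 and 1.35 at 10, and miR9555 gave -6.14 at 0.1. Taking each library's own 3 most abundant miRNAs, which differ in 1 member (novel_37 in the autotetraploid, novel_23 in the doubled haploid library), the share of the listed total was 87.2% in the autotetraploid and 80.6% in the doubled haploid library, and at 100 RPM or more Pearson r was 0.91 and Spearman rho 0.85. Median-ratio and TMM scaling were not run, because both take their factor from miRNAs assumed unchanged and the list holds those selected for a difference. The random matched lists were not run, since 34 miRNAs do not give 50 neighbours. Merging of identical sequences could not be run, as the table gives none and repeats no name. With 1 library per group no replicate could be left out. No paired analysis was possible because each group had 1 library.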

Other observations

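All tests in this part were chosen after the values they concern had been seen.

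Both arms of the miR398 hairpin and the listed arm of miR408 were higher in the autotetraploid library by ratios of 3.47 to 4.01. The lowest interval bound of the 3 rows was 2.46, which argues against counting error. It was 2.18 after the larger of the scaling shifts at hand was taken away, but scaling stays open, because the list holds only miRNAs selected for a difference and those shifts do not measure it. The ratios of the 3p and 5p arms of miR398 differed by a factor of 1.15, with an exact 95% interval from 0.799 to 1.62, so a single factor acting on the hairpin as a whole, or on the library, may account for both arms, although a difference of up to that size between them is not excluded. Whether the difference goes with ploidy or with variation between plants or libraries cannot be told apart, because each group had 1 library. A candidate biological explanation is a difference in copper status, which was not tested, because miR397, miR857 and the target transcripts were not analysed here.

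The deposited p-values can be rebuilt from the deposited values. A normal test of the log ratio given the mean log intensity, with RPM entered as if they were reads and 1 fitted centre, gave all 30 p-values above 0 to within 0.0116 on the log10 scale. The same test on implied reads, with a centre fitted anew to them, missed by up to 67.4, and the test on RPM centred on equal values by up to 59.3, so both of these are argued against. The fitted centre was 0.18 on the log2 scale, an autotetraploid to doubled haploid ratio of 1.13, and a scale factor applied on top of the library totals is a candidate source, since neither normalising total was a whole number (the nearer by 0.213 of a read). With 1 read entered as 2.21 or 2.32, counting error is understated: on implied reads the same formula gave 9 of the 34 miRNAs a p-value above the largest one deposited, with the centre at equal RPM and with the fitted centre, and these are the same 9 whose counting intervals include 1.

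bra-miR9552a-3p and bra-miR9552b-5p were the only pair of the 561 pairs of listed miRNAs with identical values in both libraries. Their genes, MIR9552A and MIR9552B, share 155 bases in the RefSeq annotation and are the only overlapping pair among 88 annotated miRNA genes. The same reads may therefore have been counted under both names, in which case the list holds 1 fewer lower miRNA (7 in place of 8 at 10 RPM or more). Both rows rested on few reads and are named for opposite arms, so a coincidence was not excluded. No sequence was given that would settle whether reads were shared.

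The q-values carry information on miRNAs outside the list. The ratio of q-value to p-value in the authors' deposited table equals 38.9 divided by a whole number for each p-value above 1e-04, to within 0.0022 of that whole number. A rank among all tested miRNAs would give this. The value 38.9 was fitted to these same rows. Among the smaller p-values, bra-miR172c-3p departed from a whole number by 0.46. If the whole numbers are ranks, the last listed miRNA, bra-miR172b-5p, held rank 91, so 57 miRNAs outside the list had a p-value no larger than its 0.022497. They were not analysed here, and the direction and size of their differences are unknown. Every listed miRNA differed by at least 2-fold, which these need not have done.

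The arm of miR408 listed was 5p, the most abundant row of the table, while the arm best known for silencing copper protein transcripts in other plants is 3p. The less abundant arm made up 0.899% of the reads of both miR398 arms in the autotetraploid and 1.03% in the doubled haploid library. For miR172c the 5p arm made up 9.71% and 2.56%, on 10 reads and 1 read.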
